A study of Homo sapiens with 23 samples.

How the data were processed

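RNA sequencing libraries of monocytes and T cells from the blood of people undergoing cardiac surgery were analysed from processed files alone. Per the labels, blood was drawn before surgery, at 24 h and at 3 months, mononuclear cells were separated on a density gradient, and monocytes were purified by negative selection against B cells, NK cells and T cells. How the T cells were purified is not given in the sources used here. The submitters' processing notes name cutadapt, STAR, featureCounts, MultiQC and DESeq2, with no versions and no settings. The genome build, the gene annotation, the strandedness and the handling of reads that map to several places are not given in the sources used here. Genes that share sequence with near-identical copies are therefore uncertain where they are named.

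The authors deposited 1 expression table with a column per library, named as FPKM. Its values proved to be CPM, with each count as a share of the total over the genes listed, not of all reads of the library. Every deposited column sums to the total that defines CPM over the genes listed for that library, and the deposited CPM values do not depend on gene length. Below 2000 reads, 100.0% of the values in every library are whole multiples of what 1 read is worth, within a tolerance of 0.01 reads, so whole reads were recovered. The recovered depth, which covers the listed genes only, ran from 0.693 to 11.7 M reads (M for mega) per library, with a median of 3.06 M. A count of 0 allows up to 3 reads, and this floor covers counting error only. The table lists 6552 genes, of which 6537 (99.8%) matched a reference annotation by name and 6531 lie on chromosomes 1, 10, 11, 12, 13 and 14. Genes of other chromosomes were not analysed here except where the authors' own comparison tables list them. A value is given in all 23 libraries for 6283 genes. The other 269 genes, 268 of them on chromosome 14, have no value in some libraries and were left out of the tests. No value column was left unmatched to a sample, and 1 line without a gene name was left out.

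The authors also deposited comparison tables for monocytes at 24 h, monocytes at 3 months against both earlier times, and monocytes against T cells before surgery. They list 560, 564, 559 and 558 genes, and the rule by which genes were selected is not given in the sources used here. Per the file headers they hold a base mean of normalized counts, a log2 fold change with its standard error, a Wald score, a p-value with its adjusted p-value, and the −log10 of the p-value. Their log2 fold changes were turned so that the later time, or monocytes, come first. Values from these tables are named as the authors' own and were used only beside the tests made here.

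Libraries were grouped by cell type and time from the labels. For 1 library the time labels contradict each other; it was kept in the group that its title gives, and each comparison it enters was repeated without it. The 23 libraries come from 13 donors, and some donors were sampled more than once. Before surgery and 24 h share 3 monocyte donors, before surgery and 3 months share 2, 24 h and 3 months share 3, and the T cell groups share 2. Deviations from the group mean correlated between libraries of the same donor at 0.14 to 0.32 for before surgery and 24 h, 0.25 to 0.26 for before surgery and 3 months, −0.08 to 0.05 for 24 h and 3 months, and −0.44 to 0.22 for T cells. The pairing comes from the donor numbers in the labels. A fit with the donor as a block was run beside each comparison that shares donors. No pair of libraries in a group matched within sampling noise: the lowest chi-square per degree of freedom was 7.94.

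The main test was limma 3.58.1 (lmFit and eBayes with a mean-variance trend, R 4.3.3) on log2(CPM + 1), with Benjamini-Hochberg adjustment and a threshold of 0.05. A gene was tested with at least 1 CPM in as many libraries as the smaller group holds. Fold changes are on the log2(CPM + 1) scale, which understates the change of genes with low values. The 3 monocyte groups shared 1 fit; every cell type comparison and the T cell comparison used only their own groups; the difference between cell types was an interaction term over 4 groups. This design was written for FPKM values, and the same test was applied to the CPM values. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0; of these only DESeq2 for the 24 h comparison was planned before the data were seen.

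The groups, tests, alternatives, rule for named genes and 34 gene lists were fixed before the data were examined. A list with at least 5 tested members was tested with camera (preset correlation 0.01), again with an estimated correlation, and with fry. Camera compares a list with the other genes tested, and fry asks whether its members move one way on balance. The mean log2(CPM + 1) of a list per library was compared between groups with two-sided exact permutation tests. These tests treat all libraries as independent and take no account of donors sampled more than once. For each list the number of members past the threshold is also given adjusted over the list alone. Named genes are the 10 largest changes in each direction among genes past the threshold with at least 5 CPM in the higher group and every library of that group above the median of the other, then up to 4 members of each list by smallest p, and up to 5 genes of each deposited table. Where no gene passed, the 5 with the smallest p are named. Sex-linked marker genes, genes without a symbol and rearranged antigen receptor segments were left out of the names.

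The tests were tried on simulated counts with the depths of the real libraries. In the simulated 24 h comparison over 3854 genes, limma recovered 16% of genes changed 2-fold, 78% of those changed 4-fold, 88% of those changed 8-fold and 98% of those changed 16-fold, and 4.8% of its calls were unchanged genes. For T cells over 4318 genes the recovered shares were 16%, 58%, 88% and 90%, with 6% of calls unchanged. For monocytes against T cells over 4113 genes they were 16%, 80%, 94% and 98%, with 6.5% unchanged. For the interaction over 4489 genes they were 4%, 26%, 66% and 68%, with 6.8% unchanged. In each simulated comparison camera called the 1 changed list and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. The simulation therefore says nothing of false camera calls for lists whose members vary together. The estimated correlation of the interferon-stimulated list at 24 h was 0.429.

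Alternatives covered a pseudocount of 0.1, no filter and a filter at 5 CPM, median-ratio and quantile scaling, no trend, array weights, the groups in the fit, the donor as a block or a random effect, the other tools, and leaving out each library in turn. Monocyte libraries also fell into sets by the levels of pseudogenes, seen in the data and called read-assignment sets here. The cause of the sets was not tested. No donor had libraries in both sets, so a donor block also takes up the set. Set membership as a term, each set alone, and the fit without 2 libraries with low TPT1 were added after the sets were seen.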

Results

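Gene expression was measured by RNA sequencing in monocytes, the circulating phagocytes of the innate immune system, and in T cells, lymphocytes of the adaptive immune system, from people undergoing cardiac surgery. Monocytes were sampled before surgery, at 24 h and at 3 months, with 5 libraries at each time. T cells were sampled before surgery (5 libraries) and at 3 months (3 libraries). The question in the study's title is how blood leukocytes respond to surgery acutely and after recovery. Recovered depth counts reads on the listed genes only. It was 2.66 to 10.8 M reads (M for mega) per monocyte library before surgery, 2.84 to 11.7 M at 24 h and 3.00 to 6.21 M at 3 months. For T cell libraries it was 0.693 to 3.06 M reads before surgery and 1.80 to 2.22 M at 3 months. Between 3411 and 3929 genes reached 1 CPM in monocyte libraries and between 3913 and 4548 in T cell libraries. The expression table covers chromosomes 1 and 10 to 14, so gene groups are seen through their members there.

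Monocyte libraries fell into a set A of 7 and a set B of 8 by RPL13AP5, a ribosomal protein pseudogene, which was at most 418 CPM in set A and at least 1749 CPM in set B. A gap of over 1 log2 unit separated the sets at 17 genes, 11 of them pseudogenes (64.7%, against 2.8% of the genes tested). RPL13AP5, which defined the sets, is itself among these genes. No gene with such a gap appeared in any of 100 random splits, which were not chosen by a gap in any gene. Set A held 1 library from before surgery, 2 from 24 h and 4 from 3 months, so set and time overlap in part. No donor had libraries in both sets, so a difference between the sets cannot be told apart from a difference between donors. In 2 of the 3-month libraries (replicates 2 and 5), TPT1, an abundant translationally controlled mRNA, was at most 1762 CPM, against at least 6652 CPM elsewhere.

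The first comparison asked what changed in monocytes 24 h after surgery. CD163, LYVE1 and MS4A4A were among the genes that rose, and some interferon-stimulated, immediate-early and lymphocyte genes fell. CD163, the receptor that clears haemoglobin bound to haptoglobin, rose from 1668 ± 185 CPM before surgery to 7828 ± 7304 CPM at 24 h (SD, n = 5 each; log2 change 1.81, SE 0.46, limma adjusted p = 0.038). LYVE1, a hyaluronan receptor, rose from 1.23 ± 1.09 to 27.2 ± 19.2 CPM, and MS4A4A, a membrane protein of macrophages, from 65.2 ± 24.5 to 389.5 ± 155 CPM. IFI44L, an interferon-stimulated gene, fell from 175 ± 121 to 8.96 ± 6.06 CPM (log2 change −4.03, SE 0.48, limma adjusted p = 0.000231). NR4A1, an immediate-early nuclear receptor, fell from 1496 ± 1458 to 15.9 ± 12.6 CPM (log2 change −5.56, SE 1.02, limma adjusted p = 0.00585).

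Of 3824 genes tested with limma, 19 rose and 99 fell at 24 h, and 734 had an unadjusted p under 0.05. The median log2 change of all genes was −0.32, and the changes of lists are best read against it. Scaling moved the split: median-ratio scaling gave 27 higher and 54 lower genes, and quantile normalization 21 and 33. DESeq2 gave 89 and 152, and edgeR 19 and 31. Other genes that rose were TMT1B (log2 change 4.93, SE 0.89), the endothelin receptor gene EDNRB (3.09, SE 0.60), the integrin gene ITGA7 (2.94, SE 0.59), the secreted protease gene HTRA1 (2.43, SE 0.39) and NMNAT2 (2.13, SE 0.41). With the donor as a block, CD163 kept its log2 change (1.86) and lost its call (limma adjusted p = 0.127), as did the complement gene C1QC (2.02, adjusted p = 0.122), MYO7A (1.57, adjusted p = 0.0651) and the vasodilator peptide gene ADM (1.66, adjusted p = 0.072). CD163 and C1QC also lost their calls with no filter and in most fits with 1 library left out. So did CD163 with quantile normalization and with all 5 groups in the fit, and C1QC and NMNAT2 with edgeR.

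Among 15 interferon-stimulated genes, 6 fell and none rose over all genes, and 12 fell and 1 rose adjusted over the list alone. IFIT2 fell by 3.30 log2 units (SE 0.37, limma adjusted p = 0.000196), IFIT1 by 2.98 (SE 0.44), OAS3 by 2.45 (SE 0.56) and EPSTI1 by 2.26 (SE 0.36). The list was lower than other genes by camera (adjusted p = 9.19e-08; adjusted p = 0.104 with an estimated correlation), and its members fell on balance by fry (adjusted p = 0.00496). Its mean level was 5.71 ± 0.33 at 24 h and 7.35 ± 0.79 before surgery (log2(CPM + 1), n = 5 each; exact permutation p = 0.00794, the smallest possible, adjusted p = 0.027). Among 10 genes of phagocytosis, Fc receptors and complement, C1QC rose over all genes (log2 change 2.07, SE 0.54), and 3 rose adjusted over the list alone; the complement receptor gene CR1 had a log2 change of 1.14 (SE 0.32, limma adjusted p = 0.062). This list was higher by camera (adjusted p = 9.19e-08, and adjusted p = 0.0316 with an estimated correlation, a call that ends with the donor block (0.0863), with median-ratio scaling (0.14) and without the libraries with low TPT1 (0.0611)). Its mean level was 7.99 ± 0.37 against 7.12 ± 0.32 (exact permutation p = 0.00794, adjusted p = 0.027). FCGR1A, FCGR2B and FCGR3A in this list share sequence with near-identical copies and are uncertain.

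No gene of the 6 tested alarmins passed over all genes, and 4 rose adjusted over the list alone. S100A12, a calgranulin of classical monocytes, had a log2 change of 2.11 (SE 0.62, limma adjusted p = 0.0709), and ALOX5AP, which serves leukotriene synthesis, of 1.78 (SE 0.57, limma adjusted p = 0.09). The list was higher by camera (adjusted p = 1.51e-06; adjusted p = 0.104 with an estimated correlation), and its mean level was 13.04 ± 0.33 against 11.8 ± 0.33 (exact permutation p = 0.00794, adjusted p = 0.027). Of 7 classical monocyte markers, 3 rose adjusted over the list alone (camera adjusted p = 3.85e-05; adjusted p = 0.104 with an estimated correlation). Of 6 non-classical monocyte markers, MS4A7 (log2 change −1.37, SE 0.24) and RHOC (−1.55, SE 0.37) fell, and 5 fell adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.104 with an estimated correlation; fry adjusted p = 0.00524). Of 6 immediate-early genes, a group that also responds to sample handling, NR4A1 and EGR2 (log2 change −3.19, SE 0.59) fell, and 4 fell adjusted over the list alone (camera adjusted p = 0.00257; adjusted p = 0.16 with an estimated correlation). PTGS2, the inducible prostaglandin synthase (−2.98, SE 0.75), and BIRC3, a target of NF-kB (−3.11, SE 0.43), also fell.

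Markers of lymphocytes were low in all monocyte libraries and lower at 24 h. Of 9 T cell markers, CD6 (log2 change −2.52, SE 0.53) and CD247 (−2.88, SE 0.69) fell, and 6 fell adjusted over the list alone. The T cell list level was 1.35 ± 0.80 at 24 h against 3.17 ± 1.04 (exact permutation p = 0.0159, adjusted p = 0.0338), with a camera adjusted p = 0.000684, and adjusted p = 0.165 with an estimated correlation. Of 6 cytotoxic and NK cell markers, 3 fell, among them PRF1, the pore-forming protein (−3.81, SE 0.84), and KLRB1 (−3.06, SE 0.71); the list had a camera adjusted p = 0.000194, and adjusted p = 0.16 with an estimated correlation. All 3 tested B cell markers fell: MS4A1 (−3.56, SE 0.89), FCRL1 (−2.81, SE 0.62) and FCRLA (−2.61, SE 0.59). With edgeR MS4A1, PRF1 and EGR2 lost their calls. MS4A1 also lost its call with median-ratio scaling and without the library whose time labels contradict. With the donor block CD6 (−2.05, limma adjusted p = 0.101), CD247 (−3.02, adjusted p = 0.0607), KLRB1 (−3.14, adjusted p = 0.069) and RHOC (−1.91, adjusted p = 0.0593) lost their calls, and ALOX5AP (1.95, adjusted p = 0.0302) and ATF3 (−3.37, adjusted p = 0.0077) gained one. Of 7 T cell activation genes, CD69 (−4.09, SE 0.62) and NR4A1 fell (camera adjusted p = 0.00188; adjusted p = 0.104 with an estimated correlation; adjusted p = 0.0553 with the donor block).

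The glycolysis and hypoxia list was higher relative to other genes (camera adjusted p = 0.00165; adjusted p = 0.198 with an estimated correlation), with 1 of 10 members rising, ADM (log2 change 1.63, SE 0.33). The migration receptor list was also higher (camera adjusted p = 0.00524; adjusted p = 0.104 with an estimated correlation) with no member of 5 passing. Lists of haem and iron handling (camera adjusted p = 0.0527), resolution of inflammation (0.0518), Toll-like receptor signalling (0.447), respiratory chain (0.314), cytosolic ribosome (0.082) and dendritic cells (0.798) were not called. The Toll-like receptor and respiratory chain lists had medians of −0.13 and −0.09, which camera reads as upward because all genes had a lower median. With the donor block the haem and iron list (camera adjusted p = 0.0312; adjusted p = 0.237 with an estimated correlation) and the respiratory chain list (0.0278; 0.375 with an estimated correlation) passed only at the preset correlation. Without the library whose time labels contradict, the ribosomal list was called lower (camera adjusted p = 0.0101; adjusted p = 0.25 with an estimated correlation; fry adjusted p = 0.0163) and the resolution list higher (camera adjusted p = 0.0375; 0.164 with an estimated correlation). With the set as a term the haem and iron and resolution lists passed (0.0449 each; 0.152 with an estimated correlation), and without the libraries with low TPT1 the resolution list (0.0126; 0.0916).

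The number of genes called at 24 h depended on single libraries. Leaving out 1 library at a time gave 41 to 186 genes. The count fell to 62, 48 and 41 without replicates 2, 3 and 4 from before surgery, and to 63, 46, 47 and 58 without replicates 1, 2, 3 and 4 of 24 h. Set B libraries alone gave 80 higher and 833 lower genes, and set A, with 1 library before surgery and 2 at 24 h, was not compared; with the set as a term, 20 genes were higher and 96 lower.

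**Figure D1:**
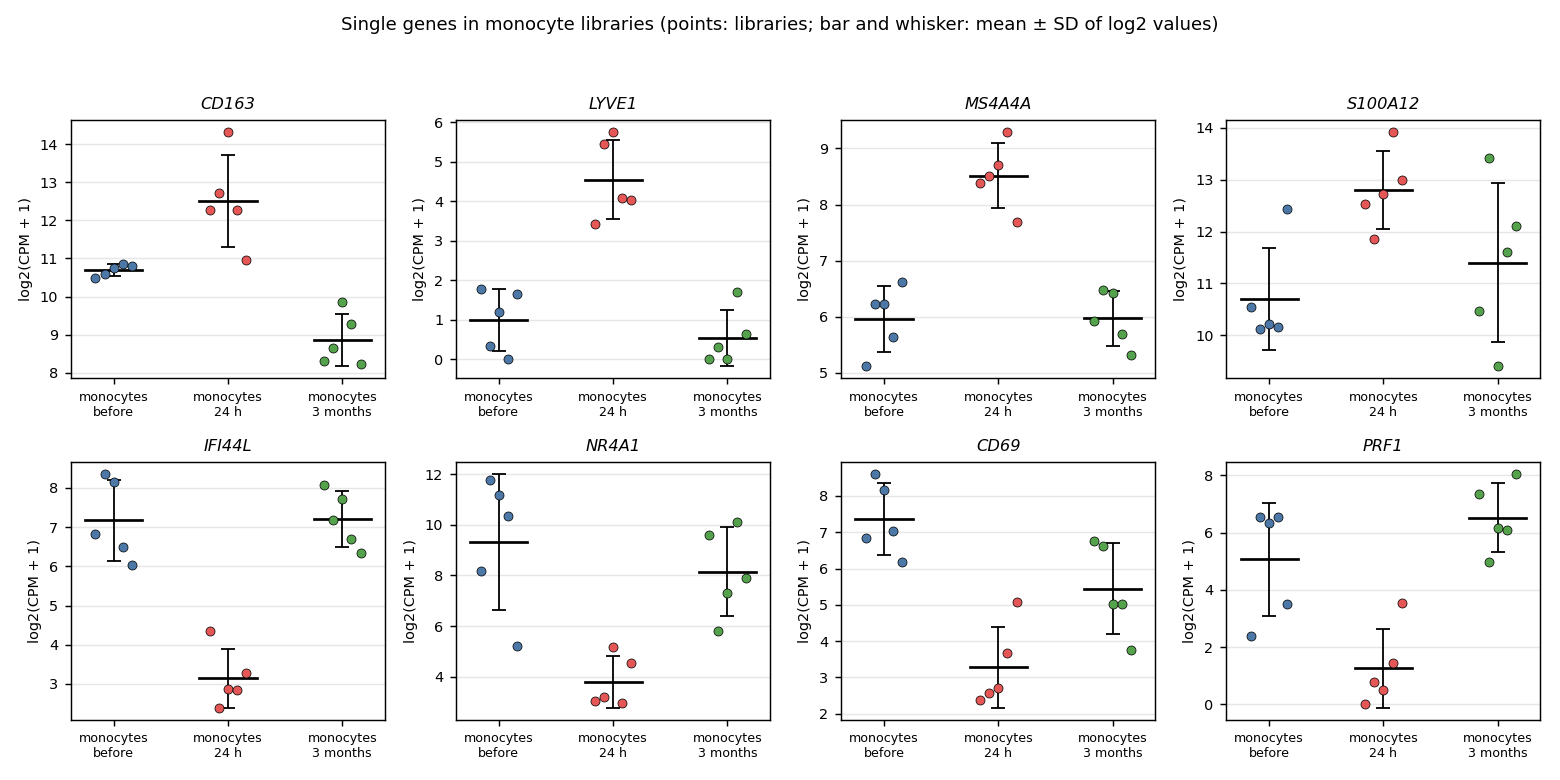
Levels of 8 genes in monocytes before surgery, at 24 h and at 3 months, with log2(CPM + 1) on the vertical axis, 1 point per library and bars for the mean ± SD (n = 5 per time). CD163, LYVE1 and MS4A4A sit highest at 24 h, while IFI44L, NR4A1, CD69 and PRF1 sit lowest there.

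The authors' deposited table for 24 h against before surgery lists genes of all chromosomes. In it 8 of 8 listed glucocorticoid-induced genes were higher at 24 h, among them VSIG4, a complement receptor (log2 change 3.84, SE 0.38), ADAMTS2 (3.21, SE 0.52) and the steroid receptor co-chaperone gene FKBP5 (1.91, SE 0.31). The authors' deposited table also has 8 of 8 alarmins, 5 of 5 phagocytosis genes and 3 of 3 neutrophil markers higher. It has 10 of 10 interferon-stimulated genes and 4 of 4 B cell markers lower. Of the 560 genes in it, 287 were higher at 24 h, and it lists 8 of the 20 genes of the glucocorticoid list. The genes with the smallest adjusted p in the authors' deposited table were C3 (−3.58, SE 0.35), VSIG4, ITGA7 (3.24, SE 0.33), SH3PXD2B (3.07, SE 0.32) and GBP5 (−2.38, SE 0.25). Of 159 genes listed in the authors' deposited table and tested here, 100% had the same direction, 65 passed with limma and 129 with DESeq2. The same libraries underlie both, so the authors' deposited table is not independent evidence.

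The comparison of 3 months with 24 h asked how monocytes moved from the acute phase to recovery. Most interferon-stimulated genes and T cell markers tested rose, and CD163, LYVE1 and HTRA1 were among the genes that fell. CD163 fell from 7828 ± 7304 CPM at 24 h to 512 ± 263 CPM at 3 months (SD, n = 5 each; log2 change −3.64, SE 0.46, limma adjusted p = 0.000208). LYVE1 fell by 4.01 (SE 0.51) and HTRA1 by 3.18 (SE 0.39). IFIT2 rose from 11.1 ± 3.32 to 168 ± 61.9 CPM (log2 change 3.77, SE 0.37, limma adjusted p = 2.62e-05), and G0S2, an inhibitor of triglyceride breakdown, from 114 ± 119 to 2970 ± 2503 CPM (4.74, SE 0.83).

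With limma 377 genes rose and 87 fell among 3824, and 1144 had an unadjusted p under 0.05; the median of all genes was 0.32. Median-ratio scaling gave 311 higher and 209 lower, quantile normalization 129 and 163, DESeq2 505 and 259 and edgeR 317 and 219. With the donor as a block 228 rose and 40 fell, and RASSF3 (log2 change −3.49, SE 0.96) moved to −2.94 with a limma adjusted p = 0.088. Of 15 interferon-stimulated genes 10 rose, and 13 rose adjusted over the list alone, among them IFI44L (4.06, SE 0.48), IFIT1 (3.35, SE 0.44) and IFIT3 (2.70, SE 0.39). The list level was 7.68 ± 0.35 at 3 months against 5.71 ± 0.33 at 24 h (n = 5 each; exact permutation p = 0.00794, adjusted p = 0.0337), with a camera adjusted p = 2.85e-07 and adjusted p = 0.176 with an estimated correlation. Of 10 phagocytosis genes 4 fell, and 6 fell adjusted over the list alone: CR1 (−2.45, SE 0.32), C1QC (−2.10, SE 0.54), C1QB (−2.06, SE 0.59) and FCGR1A (−1.80, SE 0.53; uncertain for its copies) passed over all genes. This list had a camera adjusted p = 2.87e-06, and adjusted p = 0.0692 with an estimated correlation.

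Lymphocyte markers rose from 24 h to 3 months in the same libraries. Of 9 T cell markers 7 rose, and 9 rose adjusted over the list alone, such as CD247 (log2 change 4.36, SE 0.69) and LCK (3.94, SE 0.63); the list level went from 1.35 ± 0.80 to 4.32 ± 0.66 (exact permutation p = 0.00794, adjusted p = 0.0337). The T cell list had a camera adjusted p = 3.18e-06, and adjusted p = 0.176 with an estimated correlation. Of 6 cytotoxic markers 5 rose, PRF1 by a log2 change of 5.27 (SE 0.84; camera adjusted p = 0.000132, and adjusted p = 0.228 with an estimated correlation). The B cell markers MS4A1 (3.91, SE 0.89) and FCRLA (2.68, SE 0.59) rose. Of 6 immediate-early genes, 3 rose: NR4A1 (4.37, SE 1.02), ATF3 (2.78, SE 0.83) and EGR2 (2.77, SE 0.59); camera did not call the list (adjusted p = 0.205; with the donor block 0.0219, and 0.254 with an estimated correlation). Of 6 non-classical markers 3 rose: MS4A7 (1.65, SE 0.24), TCF7L2 (1.52, SE 0.39) and RHOC (1.43, SE 0.37); camera did not call this list either (adjusted p = 0.139; with the donor block 0.0171, and 0.36 with an estimated correlation). Of the T cell activation genes 3 rose (camera adjusted p = 0.0383; adjusted p = 0.316 with an estimated correlation; adjusted p = 0.104 without the libraries with low TPT1). Camera put the classical monocyte list (adjusted p = 0.0133; adjusted p = 0.316 with an estimated correlation), the migration list (0.0133; 0.176), the glycolysis list (0.0304; 0.448) and the alarmins (0.0437; 0.448) lower than other genes; the glycolysis call ended with the donor block (adjusted p = 0.173), with the set as a term (0.178) and with median-ratio scaling (0.0504), as did the alarmin call with median-ratio scaling (0.13), while without the libraries with low TPT1 4 of 6 alarmins fell (camera adjusted p = 1.24e-06; adjusted p = 0.059 with an estimated correlation).

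With the donor block C1QC (−1.71, limma adjusted p = 0.132), C1QB (−1.63, adjusted p = 0.205), FCGR1A (−1.05, adjusted p = 0.117), RHOC (1.47, adjusted p = 0.0869) and FCRLA (1.97, adjusted p = 0.0775) lost their calls. RNU2-2P, a small nuclear RNA with near-identical copies, rose by a log2 change of 4.77 (SE 0.72) and is uncertain. Set A libraries alone (2 at 24 h and 4 at 3 months) gave 0 genes with limma and 405 at an unadjusted p under 0.05. Set B libraries alone gave 399 higher and 55 lower genes, with 1 lone 3-month library assumed to vary like the others, and the set as a term gave 317 and 68. Leaving out 1 library gave 281 to 812 genes: 281 and 291 without replicates 2 and 1 of 24 h, 306 without replicate 1 of 3 months, and 812 without replicate 3 of 3 months.

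Both comparisons use the same 24 h libraries, which by itself makes their calls overlap. The 19 genes higher at 24 h than before and the 87 higher at 24 h than at 3 months shared 14 genes; independent lists would share 0.432. The 99 and 377 genes lower at 24 h shared 66, against 9.76 for independent lists. In 100 simulations of shared libraries without effects both shared 0, which is chance with almost no calls and no baseline for lists of this length. With the 24 h libraries split between the comparisons, the shared genes numbered 1 to 7 (median 3 over 20 splits) for those higher and 3 to 19 (median 11.5) for those lower.

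**Figure D2:**
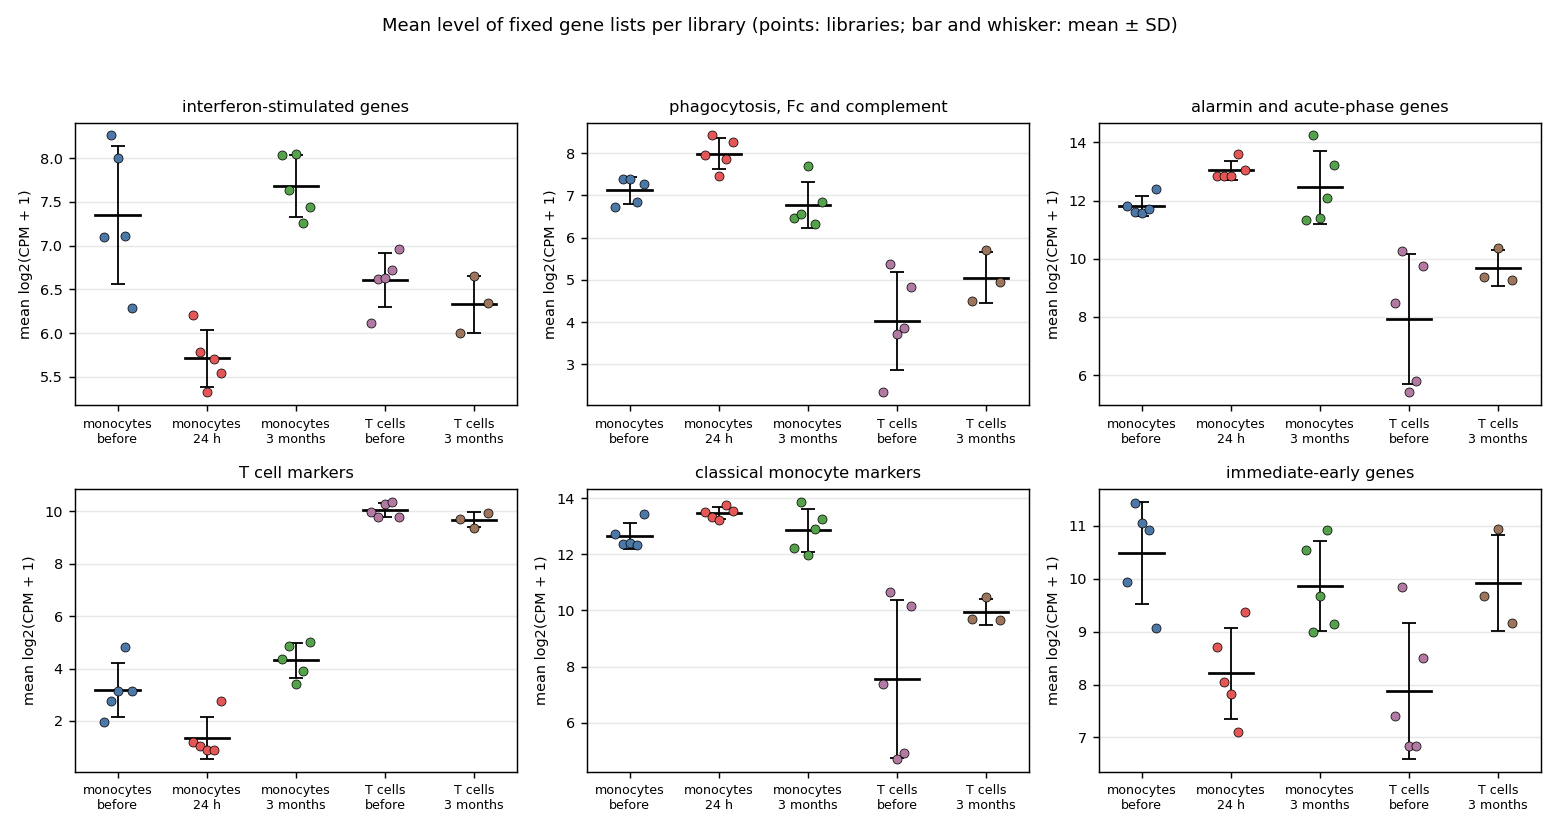
Mean log2(CPM + 1) of 6 gene lists per library in the 5 groups, with 1 point per library and bars for the mean ± SD (n = 5, and n = 3 for T cells at 3 months). The interferon-stimulated list averages 5.71 in monocytes at 24 h, against 7.35 before surgery and 7.68 at 3 months.

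In the authors' deposited table for 3 months against 24 h, 10 of 10 listed inflammatory cytokines were higher at 3 months, among them CXCL10 (log2 change 5.41, SE 0.61), CCL3 (4.15, SE 0.74) and IL1B (3.94, SE 0.60). Of the 559 genes in it, 393 were higher at 3 months, and it lists 10 of the 22 genes of the cytokine list. The authors' deposited table also has 12 of 12 interferon-stimulated genes higher and 6 of 6 glucocorticoid-induced genes lower, such as VSIG4 (−3.74, SE 0.55). Of 173 genes of the authors' deposited table that were tested here, 100% had the same direction, 165 passed with limma and 173 with DESeq2.

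The comparison of 3 months with before surgery asked whether monocytes differed after recovery. No gene passed with limma among 3824, with 732 at an unadjusted p under 0.05. The count-based tools gave calls: DESeq2 222 higher and 127 lower, and edgeR 13 and 13. The 5 genes with the smallest p all had a limma adjusted p = 0.0501. ADM was at 568 ± 124 CPM at 3 months and 152 ± 47.0 before surgery (n = 5 each; log2 difference 1.95, SE 0.33), AGO4, an Argonaute gene, at 170.2 ± 135 and 599 ± 102 (−2.14, SE 0.40), and LCP1, an actin-bundling protein of leukocytes, at 3172 ± 1800 and 8844 ± 1924 (−1.60, SE 0.33). HHLA3 and DYNLL1 differed by 2.01 (SE 0.40) and 1.68 (SE 0.33). CD163 differed by −1.83 (SE 0.46, limma adjusted p = 0.0734), with 512 ± 263 against 1668 ± 185 CPM.

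By list, the ribosomal proteins were lower by camera (adjusted p = 0.00835; adjusted p = 0.882 with an estimated correlation), with 4 of 5 members lower adjusted over the list alone and a median of −1.12; RPL5 differed by −1.18 (SE 0.31). T cell markers were higher by camera (adjusted p = 0.00835; adjusted p = 0.882 with an estimated correlation), with no member of 9 passing and a median of 1.45. No other list passed camera, the lowest adjusted p being 0.223. With the donor block the ribosomal call ended (camera adjusted p = 0.113), and interferon-stimulated genes (adjusted p = 7.42e-05, median 0.86) and alarmins (0.0274) were called higher, both with an adjusted p = 0.707 with an estimated correlation. Without the libraries with low TPT1 the alarmin median was −0.14, so the direction of that list depends on them. With the set as a term, the ribosomal (camera adjusted p = 0.253) and T cell (0.167) calls ended and the interferon list was called (2.13e-05; adjusted p = 0.75 with an estimated correlation). Without the libraries with low TPT1 the T cell call also ended (camera adjusted p = 0.419, median 0.86). Haem and iron genes had a median of 0.43 and a mean of −0.04.

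The count of genes rested on 1 library. Without replicate 3 of 3 months, the only set B library of its group, 143 genes were higher and 220 lower; without any other library the count was 0. With the set as a term limma gave 0 genes.

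**Figure D3:**
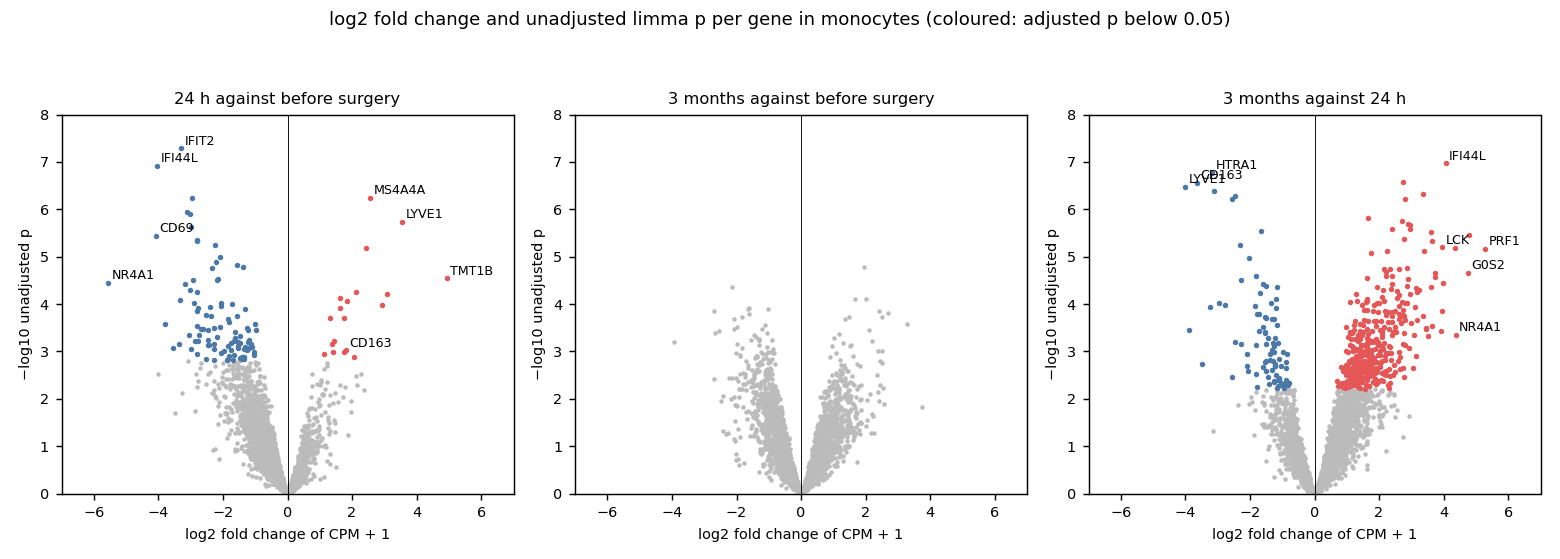
Log2 difference (horizontal, on the log2(CPM + 1) scale) against −log10 of the unadjusted p (vertical) for 3824 genes in the monocyte comparisons of 24 h with before surgery, 3 months with before surgery and 3 months with 24 h. Coloured points have a limma adjusted p under 0.05: 118, 0 and 464 genes.

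In the authors' deposited table for 3 months against before surgery, 10 of 10 listed platelet genes were higher, among them GNG11 (log2 change 2.98, SE 0.62), PPBP (2.93, SE 0.62) and PF4 (2.48, SE 0.58). The authors' deposited table has 5 of 5 listed ribosomal protein genes lower, such as RPS3A (−2.02, SE 0.60) and RPL10A (−1.33, SE 0.34). Its smallest adjusted p belonged to ITGA4 in the authors' deposited table (−1.73, SE 0.23), followed by EGLN3 (3.38, SE 0.58), H2BC8 (3.18, SE 0.54) and IRF9 (1.42, SE 0.26). Of 141 genes of the authors' deposited table that were tested here, 100% had the same direction, 0 passed with limma and 138 passed with DESeq2.

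Monocytes before surgery were compared with T cells before surgery, which describes the cell types and checks their labels. Monocytes had higher calgranulins, Fc receptors and lysozyme, and T cells had higher T cell receptor and signalling genes. LYZ, lysozyme, was at 33500 ± 8300 CPM in monocytes and 1501 ± 2111 CPM in T cells (n = 5 each; log2 difference 6.21, limma adjusted p = 0.000254). S100A8 was at 15140 ± 5481 and 912 ± 1119 CPM (6.58, SE 1.51), and FCER1G, the signalling chain of Fc receptors, at 2579 ± 1358 and 139.7 ± 159 CPM (4.74, SE 0.60). CD3E, a T cell receptor subunit, was at 19.4 ± 22.4 CPM in monocytes and 2707 ± 226 in T cells (−7.81, SE 0.63, limma adjusted p = 1.57e-06).

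Of 3924 genes limma called 642 higher and 1660 lower in monocytes, with a median of −0.58. Median-ratio scaling gave 1021 and 1081, quantile normalization 961 and 1036, edgeR 1114 and 952 and DESeq2 1073 and 1167, so the larger share lower in monocytes depended on the scaling. All 9 T cell markers were lower, such as CD6 (log2 difference −7.60, SE 0.45) and LCK (−7.58, SE 0.50; camera adjusted p = 1.11e-05, and adjusted p = 0.216 with an estimated correlation). In monocytes 9 of 10 phagocytosis genes (camera adjusted p = 1.61e-05), 6 of 7 classical markers (0.000871), 5 of 6 alarmins (0.00115), 5 of 6 non-classical markers (0.00146), 6 of 6 immediate-early genes (0.00222), 3 of 5 dendritic markers (0.00891) and 4 of 6 Toll-like receptor genes (0.0133; 1 was lower) were higher. Their adjusted p with an estimated correlation was 0.216 or 0.219. Glycolysis genes (6 higher, 2 lower; camera adjusted p = 0.0213, and adjusted p = 0.347 with an estimated correlation) and resolution genes (3 higher, 2 lower; 0.0284 and 0.219) were also called higher. Lists of haem and iron (0.0552), respiratory chain (0.0864), cytotoxic (0.137), activation (0.598) and migration (0.805) genes were not. Interferon-stimulated genes went both ways, 6 higher, such as OAS1 (2.24, SE 0.30), and 1 lower, IFITM1 (−3.87, SE 0.61; camera adjusted p = 0.0017, and adjusted p = 0.347 with an estimated correlation). All 5 ribosomal protein genes were lower in monocytes, RPS3 by −2.20 (SE 0.31), with a camera adjusted p = 0.0658. Helper and effector T cell genes were lower for 4 of 5, GATA3 by −6.09 (SE 0.58), and higher for 1, with a camera adjusted p = 0.185 and a fry adjusted p = 0.000544. NELL2 (−7.96, SE 0.72), S1PR1, which guides lymphocyte exit from tissue (−5.29, SE 0.41), and LAG3, an inhibitory receptor (−5.36, SE 0.47), were lower, and IL18 (3.97, SE 0.48) and CD1D (5.53, SE 1.07) higher. In the authors' deposited table for this comparison the smallest adjusted p belonged to TESPA1 (−5.21, SE 0.26) and CD96 (−5.43, SE 0.30), and 166 of 166 genes tested here had its direction and passed with limma.

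At 3 months monocytes were again compared with T cells (5 and 3 libraries). T cell markers were lower in monocytes, and most classical monocyte markers and interferon-stimulated genes higher. NELL2 was at 2.18 ± 1.56 CPM in monocytes and 783 ± 171 in T cells (log2 difference −8.08, SE 0.54, limma adjusted p = 4.39e-06), and CD69, an activation marker, at 56.2 ± 43.3 and 2983 ± 1247 CPM (−6.00, SE 0.64). NFE2, a transcription factor of the megakaryocyte and erythroid lineages, was at 650.4 ± 426 and 20.2 ± 5.85 CPM (4.76, SE 0.48), and CLEC1B, a platelet receptor, at 98.5 ± 70.3 and 1.21 ± 1.05 CPM (5.20, SE 0.78).

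Limma called 391 genes higher and 886 lower in monocytes at 3 months, with a median of −0.39. Median-ratio scaling gave 549 and 739, quantile normalization 654 and 671, edgeR 628 and 566 and DESeq2 809 and 669. All 9 T cell markers were lower (camera adjusted p = 1.54e-07), 10 of 15 interferon-stimulated genes were higher and 1 lower (7.01e-06), 6 of 7 classical markers were higher (3.08e-05) 5 of 5 ribosomal protein genes were lower (0.00208), 4 of 10 phagocytosis genes were higher (0.000251) and 4 of 5 dendritic markers were higher (0.00332); each of these had an adjusted p = 0.206 with an estimated correlation. Alarmins were higher for 4 of 6 (camera adjusted p = 0.000251; adjusted p = 0.218 with an estimated correlation). Toll-like receptor (camera adjusted p = 0.023), haem and iron (0.0259), resolution (0.0319) and non-classical (0.0468) lists were also called higher, and cytotoxic (0.0259), helper (0.0272) and activation (0.0272) lists lower, none with an estimated correlation (adjusted p = 0.206 to 0.305). Glycolysis (0.369), respiratory chain (0.14), immediate-early (0.574) and migration (0.574) lists were not called. The read-assignment sets were found among monocytes, and all T cell libraries were counted in set B. With the set as a term the comparison therefore rested on 1 monocyte library, replicate 3. There CLEC1B differed by 2.94 log2 units and TRIM58 by 4.17. The count was 554 and 661 without replicates 1 and 3 of T cells at 3 months, and up to 1475 without replicate 3 of monocytes.

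T cells at 3 months were compared with T cells before surgery (3 and 5 libraries). No gene passed with limma among 4131, with 250 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 2. DDIT4, a stress-induced inhibitor of mTOR signalling, was at 1875 ± 798 CPM at 3 months and 449 ± 283 before surgery (log2 difference 2.15, SE 0.43, limma adjusted p = 0.763). IQSEC3 (−2.85, SE 0.64), VWA5A (−1.44, SE 0.33), NID1 (2.69, SE 0.63) and THEMIS2 (1.16, SE 0.29) had the same adjusted p. With the donor as a block, over 2 shared donors and with 1 residual degree of freedom, 82 genes were higher and 18 lower, among them DDIT4 (3.04, limma adjusted p = 0.0086), NID1 (3.81, adjusted p = 0.0216), IQSEC3 (−4.03, adjusted p = 0.0239), THEMIS2 (1.58, adjusted p = 0.0474) and 6 of 7 classical monocyte markers. Without replicate 1 from before surgery 1 gene passed, and without any other library 0.

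Several lists were higher in T cell libraries at 3 months by camera: immediate-early genes (median log2 difference 1.78, adjusted p = 9.18e-07), non-classical monocyte markers (1.03, 0.000452), classical monocyte markers (3.21, 0.000564), phagocytosis genes (0.81, 0.000564), T cell activation genes (0.00279), alarmins (1.81, 0.00378), glycolysis genes (0.0155) and helper T cell genes (0.0268). T cell markers were lower (−0.42, 0.0224). None held with an estimated correlation (adjusted p = 0.247 to 0.404) or by fry (lowest adjusted p = 0.494), and no list level passed (lowest exact permutation p = 0.0714, adjusted p = 0.414; smallest possible 0.0179). Over all genes 0 members passed, and 1 immediate-early and 2 activation genes were higher adjusted over the list alone. Monocyte RNA was present in T cell libraries: the mean log2(CPM + 1) of monocyte genes outside the lists ran from 2.40 to 6.74 over the 8 T cell libraries.

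The difference between cell types in the change from before surgery to 3 months was tested as an interaction. No gene passed with limma, with 587 at an unadjusted p under 0.05; edgeR called 0 and DESeq2 60 higher and 29 lower. NID1 had the smallest p (log2 difference −4.18, SE 0.76, limma adjusted p = 0.0933), and it passed with median-ratio scaling (−4.25, adjusted p = 0.0309). By camera immediate-early genes (adjusted p = 0.000538), phagocytosis genes (0.00491), non-classical (0.00491) and classical (0.0154) monocyte markers and ribosomal proteins (0.0114) changed less, or further down, in monocytes than in T cells, and T cell markers (0.00491) the other way. With an estimated correlation the adjusted p was 0.428, and 0.476 for classical markers. The classical call ended without the library whose time labels contradict (camera adjusted p = 0.0845). Without the libraries with low TPT1 the T cell marker call ended (camera adjusted p = 0.125). In that fit alarmins were called instead (camera adjusted p = 0.0109, and 0.38 with an estimated correlation). The count was 46 without replicate 3 of monocytes at 3 months and also 46 without replicate 2 of T cells before surgery, and 1 without replicate 1 of T cells before surgery.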

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

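The tests of explanations in this part were chosen after the patterns were seen, except the interaction tests of the lists, which were planned. Markers of lymphocytes were lower in monocyte libraries at 24 h, the T cell list by a median log2 change of −2.08. A candidate explanation is less RNA of lymphocytes left in the 24 h libraries. The 73 other genes that are at least 4 log2 units higher in T cells had a median change of −1.06, with 84.9% below the median of all genes, as less lymphocyte RNA would give; negative selection of monocytes should have removed these cells. Of the 99 genes that fell, 52 are higher in T cells, 24 are higher in monocytes and 23 are called in neither direction. Among all genes of the limma comparison of cell types before surgery, more were also called higher in T cells than in monocytes. This split by itself therefore does not single out lymphocyte RNA. Whether fewer such cells passed the selection at 24 h or fewer circulated was not tested, and with the T cell level as a term 0 genes passed, since that level nearly follows time.

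Interferon-stimulated genes were lower in monocytes at 24 h. Less lymphocyte RNA is argued against for T cells only: the members that fell were higher in monocytes than in T cells before surgery, by a median of 1.38 log2 units. They were picked by a fall from those same monocyte libraries, which raises this difference. Over all 15 tested members the median was 0.84, with 6 called higher in monocytes and 1 lower. B cells and NK cells were not compared, so less RNA of these cells stays open. A split of the libraries by set is argued against, since 6 members fell with the set as a term and 6 without it. A few abundant genes taking more of the reads is argued against too, since the list median was −1.46 with median-ratio scaling, against −1.73. Lower interferon signalling after surgery may therefore be part of the pattern, but only as a hypothesis from the same data, which hold no measure of signalling apart from this list; a shift between monocyte subsets, with non-classical markers also lower, was not tested and stays open.

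Camera called the monocyte, phagocytosis and immediate-early lists higher in T cell libraries at 3 months than before surgery. These calls held at the preset correlation only (camera adjusted p = 0.247 to 0.319 with an estimated correlation). The groups overlap: the classical monocyte level was 9.67 to 10.47 at 3 months, and before surgery 10.66 and 10.16 in replicates 2 and 5 and 4.71 to 7.37 in the other 3. In both donors sampled at both times the classical and the immediate-early levels were higher at 3 months. A candidate explanation is more RNA of monocytes in these libraries. The 58 other genes at least 4 log2 units higher in monocytes had a median change of 2.13, with 100% above the median of all genes. These genes were chosen by low values in the same T cell libraries from before surgery, which by itself raises their change. With the monocyte level as a term the immediate-early list was no longer called (camera adjusted p = 0.103) and its median moved from 1.78 to 0.45. How the T cells were purified is not given in the sources used here, and a change of immediate-early genes within T cells stays open.

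The interaction test set apart 6 lists, whose change to 3 months differed between monocytes and T cells: phagocytosis genes (camera adjusted p = 0.00491), ribosomal proteins (0.0114), immediate-early genes (0.000538), classical (0.0154) and non-classical (0.00491) monocyte markers and T cell markers (0.00491). None held with an estimated correlation (adjusted p = 0.428 to 0.476). The classical call also ended without the library whose time labels contradict, and the T cell marker call without the libraries with low TPT1. The classical, non-classical and phagocytosis lists had median changes of 3.21, 1.03 and 0.81 in T cells. In monocytes these were 0.13, −0.64 and −0.57. Whether monocyte RNA in the T cell libraries gave these differences was not tested.

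By Dixon's ratio (the gap to the nearest library over the range of the group, at its 5% critical value), single libraries stood apart in 31 of 332 groups of values (9.3%); that level flags about 1 in 20 by chance for normal values. Values are given with the lowest and highest of the other libraries, and levels are in log2(CPM + 1). Among monocytes before surgery, replicate 5 had 10.763 M reads (M for mega) on the listed genes (others 2.655 to 3.88). It also had an alarmin level of 12.39 (11.57 to 11.81), a ribosomal level of 8.89 (10.5 to 10.89) and S100A12 at 12.43 (10.12 to 10.54). In the same library MS4A6A was at 11.64 (11.01 to 11.11) and TMT1B at 3.71 (1.07 to 1.79). Replicate 4 had a Toll-like receptor level of 8.65 (8.12 to 8.23), DOCK9 at 3.9 (1.79 to 2.27) and TMTC1 at 4.01 (6.02 to 6.52), and replicate 1 had ADM at 6.16 (7.3 to 7.57).

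Among monocytes at 24 h, replicate 5 had a T cell marker level of 2.77 (0.88 to 1.19), CD247 at 3.26 (0.44 to 0.98), KLRK1 at 2.92 (0.4 to 1.12), MS4A1 at 5.06 (1.04 to 2), ABCD2 at 0.56 (0 to 0.12), LINC00402 at 0.25 (0 in the others) and PEAR1 at 4.93 (2.48 to 3.15). Replicate 4 had 33.7% of its reads on the listed genes in its top 10 genes (19.6 to 22.4%). It also had an alarmin level of 13.61 (12.83 to 13.04) and S100A8 at 16.6 (15 to 15.24). In the same library RGS18 was at 9.34 (8.23 to 8.46) and PDE4B at 2.71 (5.14 to 5.66). Replicate 3 had BIRC3 at 2.91 (4.77 to 5.29). Among monocytes at 3 months, replicate 2 had 3654 genes at 1 CPM or more (3790 to 3824) and replicate 3 a glycolysis level of 10.82 (8.43 to 8.81).

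Among T cells before surgery, replicate 1 had a migration receptor level of 9.59 (10.79 to 11.05), ABCD2 at 6.5 (7.16 to 7.35), IFIT2 at 3.27 (5.66 to 6.24) and PDE4B at 7.21 (8.61 to 8.91), and replicate 2 had CLEC1B at 2.53 (0 to 0.69) and PDZK1IP1 at 2.27 (0 in the others). Outside the tests, 122 genes with values in some libraries only were above the 3 reads that a count of 0 allows in at least 1 library. Among them PSME1 had a value in 3 of 5 monocyte libraries at 24 h, at 377.1 to 552.3 CPM, and SLC7A7 in 3 of 5 there, at 1015.6 to 1605.3 CPM.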

How the results depend on the processing

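The count tools (except DESeq2 at 24 h), the read-assignment set and the fits without the libraries with low TPT1 were chosen after the data were seen; the other settings were planned. Over all settings 117 of 174 counts stayed within 1.5 times the main count. For 24 h against before surgery 9 of 28 did, and for 3 months against 24 h 17 of 28. Between the cell types it was 21 of 21 before surgery and 17 of 20 at 3 months. Where no gene passed in the main fit, only another fit without calls could count. There it was 15 of 26 for 3 months against before surgery, 15 of 20 for T cells and 23 of 31 for the interaction. Of 18689 values of named genes, 17565 kept their side of the threshold, 619 gained a call, 500 lost it and 5 turned. Of 659 list values 526 kept their side, 27 gained, 104 lost and 2 turned. A turn was counted only where a value was called in the main or the alternative fit. Values called in neither may therefore have changed direction. Except where given here, the cause was not tested.

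For 24 h against before surgery (118 genes) the count was 67 with no filter, 54 with quantile normalization, 1250 with array weights, 186 without the library with contradicting time labels, 491 with only those groups in the fit, 187 with the donor as a random effect, 241 with DESeq2, 50 with edgeR, 52 with edgeR's other scaling factors, 913 in set B, 344 without the libraries with low TPT1, and 41 to 186 with 1 library left out. For 3 months against before surgery (0 genes) it was 1 with no filter, 13 at 5 CPM, 40 with median-ratio scaling, 58 with quantile normalization, 314 with array weights, 29 with all groups, 19 with the random effect, 349 with DESeq2, 26 with edgeR, 1 without the libraries with low TPT1, and 0 to 363 with 1 left out. For 3 months against 24 h (464 genes) it was 292 with quantile normalization, 989 with array weights, 242 with only those groups, 268 with the donor as a replicate block, 764 with DESeq2, 0 in set A, 914 without the libraries with low TPT1, and 281 to 812 with 1 left out.

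For T cells at 3 months (0 genes) it was 811 with array weights, 2 with all groups, 100 with the donor as a replicate block, 2 with DESeq2, and 0 to 1 with 1 left out. For monocytes against T cells it was 1999 to 2424 before surgery (2302 genes) with 1 left out, and at 3 months (1277 genes) 398 with the set as a term and 554 to 1475 with 1 left out. For the interaction (0 genes) it was 3 with median-ratio scaling, 1 with quantile normalization, 868 with array weights, 2 with all groups, 89 with DESeq2, and 0 to 46 with 1 left out. In set B alone, with 1 library at 3 months, the log2 change from 24 h turned for TMT1B (0.17), CD1D (−1.15), MKI67 (3.87) and S100A4 (−1.36), values that rest on that library. With array weights SELENBP1 turned between the cell types before surgery (1.21). Without the libraries with low TPT1 the respiratory chain list was lower at 3 months than before surgery (camera adjusted p = 0.0274; 0.782 with an estimated correlation), than at 24 h (0.00379; 0.139) and in the interaction (0.046; 0.38).

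Beyond the calls given with each comparison, the donor block called the resolution list in T cells at 3 months (camera adjusted p = 0.0218; 0.715 with an estimated correlation); it changed no other camera call at the preset correlation, but ended fry calls, among them T cell (adjusted p = 0.0846), cytotoxic (0.0724), phagocytosis (0.123) and activation (0.0724) genes at 24 h, and phagocytosis (0.09) and activation (0.0762) genes from 24 h to 3 months; the calls of printed genes that it changed are given with them. With 3 libraries at 3 months, the T cell comparison recovered 58% of simulated 4-fold changes.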

Other observations

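The tests of other splits in this part were written after the counts were known. Single genes of coagulation and lipid mediator pathways changed in monocyte libraries between 24 h and 3 months. Too few coagulation genes were tested for a list. F5, coagulation factor V, fell from 816.7 ± 366.8 to 214.2 ± 52.33 CPM (SD, n = 5 each; log2 change −1.85, SE 0.38, limma adjusted p = 0.00502), and PLAU, the urokinase gene, rose from 1.458 ± 1.451 to 33.75 ± 34.51 CPM (3.35, SE 0.71). GPR18, a receptor for lipid mediators of resolution, rose from 2.481 ± 1.856 to 27.96 ± 20.6 CPM (2.79, SE 0.56), 1 of 10 resolution genes to pass, and that list, with a median of −0.15 and a mean of 0.10, was not called (camera adjusted p = 0.28). IL23A, a cytokine subunit, rose by a log2 change of 2.64 (SE 0.70), FTH1, the ferritin heavy chain, by 1.61 (SE 0.40), and STMN1, a microtubule regulator of dividing cells, by 2.08 (SE 0.47; 1.49 and a limma adjusted p = 0.0789 with the donor block). ALPL, a neutrophil marker, fell (−2.55, SE 0.76), and HBD, a globin gene close in sequence to HBB, rose (1.79, SE 0.43). GATA3, a transcription factor of T cells, rose by 2.74 (SE 0.67). T cell markers rose in the same libraries, from a list level of 1.35 to 4.32 log2(CPM + 1). Whether these single genes, GPR18 among them, changed within monocytes or with RNA of other cells was not tested.

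Other splits of the same libraries tested whether chance can give as many calls. For 24 h against before surgery 1 of 100 splits, the real one, gave 118 genes; the highest other gave 15, and the 18 splits that part all 3 donor pairs gave at most 0, so chance alone gave no such count. For 3 months against 24 h 2 of 100 splits gave as many as 464 genes: the other, with 466, grouped mostly set A libraries, and splits that part all pairs gave at most 82. For the cell types 1 of 100 splits gave 2302 genes before surgery and 1 of 56 gave 1277 at 3 months, with at most 1 in the others. For 3 months against before surgery the real count was 0, which any split reaches (100 of 100). The splits say nothing of chance there. The highest, 374, followed the read-assignment set, which also parts the donors, so the samples hold a structure other than time. With the set as a term the count was 0. For T cells (56 of 56 splits) and the interaction (100 of 100) the real count was also 0, so the splits say nothing of chance there either. The highest was 96 for T cells, in a single split whose cause was not tested, and 1 for the interaction.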
